A study of Mus musculus with 10 samples.

How the data were processed

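The values used here are UMI counts per gene and well, as deposited by the authors in 1 table with genes by symbol and 1920 wells from 5 plates. According to the labels, cells were tagged and pooled 384 to a plate with a 5' digital gene expression protocol. The submitters' processing notes name bcl2fastq, BWA, Seurat and the mm10 build, without versions or what each was used for. How reads were counted, which annotation was used and how the CD4 cells were isolated are not given in the sources used here. Each plate was sequenced in 2 runs that the table does not keep apart, so the runs were treated as 1 library.

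The table had 23481 genes and other entries, of which 27 had names turned into dates; these held 0.129% of UMIs (0.114 to 0.143% by plate) and were left out. Of the 23454 genes used, 13864 had a UMI. Wells with at least 500 UMIs were kept, 1895 in all, and 25 were left out. The planned filter on mitochondrial counts could not be applied because the table has 0 mitochondrial genes, and no doublet caller was run. Rn45s, a ribosomal RNA precursor gene, held 6.50, 5.63, 7.43, 7.41 and 4.20% of UMIs in mouse 1 plates 2 and 3 and mouse 2 plates 1, 2 and 3. For shares of cells with a gene, each cell was thinned to 5000 UMIs, which 1578 cells had; a share of 0 is given with the limit of 3 counts.

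The contrasts, the gene lists, the rule for naming genes and most alternatives were written before the data were examined. The clustering settings and the thresholds for naming clusters were not. They were set after looking at 9 clusterings: 2 on the most variable genes, where most clusters came largely from 1 plate; 3 on rank-selected genes, where only a Th1-like cluster was recognisable; and 4 on list genes, of which the last left out Tgtp2 as a near copy of Tgtp1 and was used. With all UMIs clustered a Tfh-like class appeared that the main clustering lacks. Class names and everything that rests on them carry that choice.

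For clustering, UMIs were split at random into 50% for clustering and 50% held out for testing. Of 115 list genes detected in at least 3% of cells in every plate, 12 were left out because their counts followed those of another gene. The limit was a Pearson r of 0.25 with a gene outside the lists, or 0.5 with another list gene. It had to be reached in all plates but at most 1. Left out were Birc5, Cd8b1, Cx3cr1, Gbp6, Ifi47, Il2ra, Irgm1, Irgm2, Ly6c2, Slfn5, Tgtp2 and Tyms, of which only Tgtp2 followed a list gene. The 103 left were scaled to 10000 counts per cell, standardised within each plate, reduced to 5 principal components and clustered by the Leiden method (scanpy 1.11.5, 20 neighbours, resolution 0.5). A cluster was named when its marker score was at least 0.5, at least 3 markers were raised, and at least 1 was among its top 10 genes. Held-out UMIs remove reuse of the same molecules, but clustering genes still differ between classes by construction.

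Counts were summed per plate for the contrast of mice, and per mouse and class with the mouse as a block for the contrasts of classes. They were tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, robust) and DESeq2 1.42.0 as the alternative; a gene was called at an adjusted p under 0.05. With 2 animals, the class contrasts describe these animals. Lists were tested with camera at a correlation of 0.01 between genes, with an estimated correlation, and with fry (limma 3.58.1). Genes were named when called and of the same sign in each mouse, the 12 largest changes each way among genes at or above the median count, with up to 4 members of each list and fixed identity genes. Shares were compared by exact permutation over 10 splits of the plates. Plates 2 and 3 of the mice share only a number: deviations of equally numbered plates correlated at 0.0115 and 0.0211, so plate number was not used as a block in the contrast of mice. Data were simulated with 200 changed genes, all drawn from genes at or above the median count. On them the Th1-like contrast recovered 25.4, 62.7 and 90.9% of genes changed 2-, 4- and 8-fold (6 false of 125 calls). The Treg-like contrast recovered 20.9, 62.7 and 97.0% (3 of 123). Recovery of genes with lower counts was not tested. R 4.3.3 and Python 3.11.15 were used.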

Results

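Single CD4 T cells from the spleens of 2 C57BL/6J mice were profiled on day 18 after intraperitoneal infection with Listeria monocytogenes, an intracellular bacterium, given on days 0 and 11. Cells were placed 384 to a plate, with 2 plates from mouse 1 (plates 2 and 3) and 3 plates from mouse 2 (plates 1, 2 and 3). Each plate was sequenced in 2 runs, and the table holds 1 set of counts per plate, so the 10 deposited samples are 5 libraries here. There was no uninfected animal, and the comparisons the labels allow are between the mice and between kinds of T cell within them. The plates held 5324080 and 4776900 unique molecular identifiers (UMIs, 1 per captured transcript) in mouse 1, and 4952253, 5909642 and 3783809 in mouse 2. Of 1920 wells, 1895 had at least 500 UMIs and were kept. Their median depth per plate ran from 8982.5 UMIs in mouse 2 plate 3 to 14964 in mouse 2 plate 2, and the median number of genes per cell from 1270.5 to 1657 in the same plates.

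The cells carried T helper markers and few transcripts of other blood lineages. With every cell thinned to 5000 UMIs, Cd4, the coreceptor for MHC class II, had a UMI in 42.4% ± 0.855 (SD, n = 2 plates) of cells in mouse 1 and 44.5% ± 4.86 (SD, n = 3 plates) in mouse 2. Cd3e, a chain of the T cell receptor complex, had one in 21.6% ± 0.570 and 28.5% ± 6.34. The CD8 alpha chain gene Cd8a was seen in at most 0.667% of thinned cells in any plate (mouse 1 plate 3; exact 95% interval 0.0808 to 2.39%). The CD8 beta chain gene Cd8b1 had a UMI in 14.5% ± 3.58 and 17.2% ± 3.61 of cells, and its counts followed those of Gnal, a G protein subunit gene on another chromosome, across cells of every plate (Pearson r 0.297 to 0.519). No thinned cell had a UMI of the B cell gene Ms4a1, the macrophage gene Csf1r or the natural killer cell gene Ncr1, which allows a share of up to 0.896% in mouse 1 plate 2 and 1.00% in mouse 2 plate 3. Cd79b, a chain of the B cell receptor, had a UMI in 2.69% and 3.00% of thinned cells in the plates of mouse 1 (exact 95% intervals 1.24 to 5.04% and 1.38 to 5.62%). It had none in 322, 321 and 300 cells of mouse 2, which allows up to 0.932, 0.935 and 1.00%. The natural killer gene Klrb1c had a UMI in a mean of 2.21% and 2.38% of thinned cells, the myeloid gene Lyz2 in 0.746% and 0.962%, and the haemoglobin gene Hbb-bs in 0.649% and 1.81%. The partner of Cd79b, Cd79a, was at most 0.932%, and Cd74, which B cells express strongly, at most 0.621%. Xist, transcribed from the inactive X chromosome, had a UMI in 3.29% ± 0.412 and 3.41% ± 1.63 of thinned cells. The Y-linked genes were also seen in both mice, with means of 4.33% and 4.69% for Ddx3y, 4.34% and 3.45% for Eif2s3y, 7.86% and 2.55% for Kdm5d, and 1.96% and 1.37% for Uty. Cells of 1 animal should not carry both, so the sex of the mice cannot be read from these genes. Shares of a few percent, for these and other genes, may be background. Trac, the T cell receptor alpha constant gene, is not among the genes of the table.

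Markers of a type 1 helper response ranged from common to rare. Ccl5, a chemokine that recruits T cells and monocytes, had a UMI in 57.0% (exact 95% interval 51.5 to 62.4%) and 48.7% (42.9 to 54.5%) of thinned cells in the plates of mouse 1. In mouse 2 it had one in 21.4% (17.1 to 26.3%), 32.4% (27.3 to 37.8%) and 30.0% (24.9 to 35.5%). Nkg7, a cytotoxic granule protein, had a UMI in a mean of 31.7% of cells in mouse 1 and 27.4% in mouse 2, with plates from 20.2% to 39.7%. Ifng, the macrophage-activating cytokine, had one in 9.18% ± 1.16 and 1.45% ± 2.52. In mouse 2 all Ifng-positive thinned cells came from plate 2, and the 0 in plates 1 and 3 allows up to 0.932 and 1.00%. Id2 had one in 39.9% ± 1.34 and 27.1% ± 6.12. Tbx21, the lineage factor of Th1 cells, had one in 5.91% ± 6.25 and 2.07% ± 2.59. Foxp3, the lineage factor of regulatory T cells (Treg), had a UMI in 11.3% ± 0.454 and 8.56% ± 3.69. Cxcr5, the receptor that guides follicular helper T cells (Tfh) to B cell follicles, had one in 6.79% ± 7.71 and 4.46% ± 0.365, with 12.2% in mouse 1 plate 2 and 1.33% in mouse 1 plate 3. Il17a, the cytokine of Th17 cells, had no UMI in any thinned cell, which allows up to 0.896% of cells with a captured UMI in mouse 1 plate 2 and 1.00% in mouse 2 plate 3. Such limits do not bound the cells that express a gene, since Cd3e, which T cells share, was captured in a mean of 21.6% and 28.5%.

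**Figure D1:**
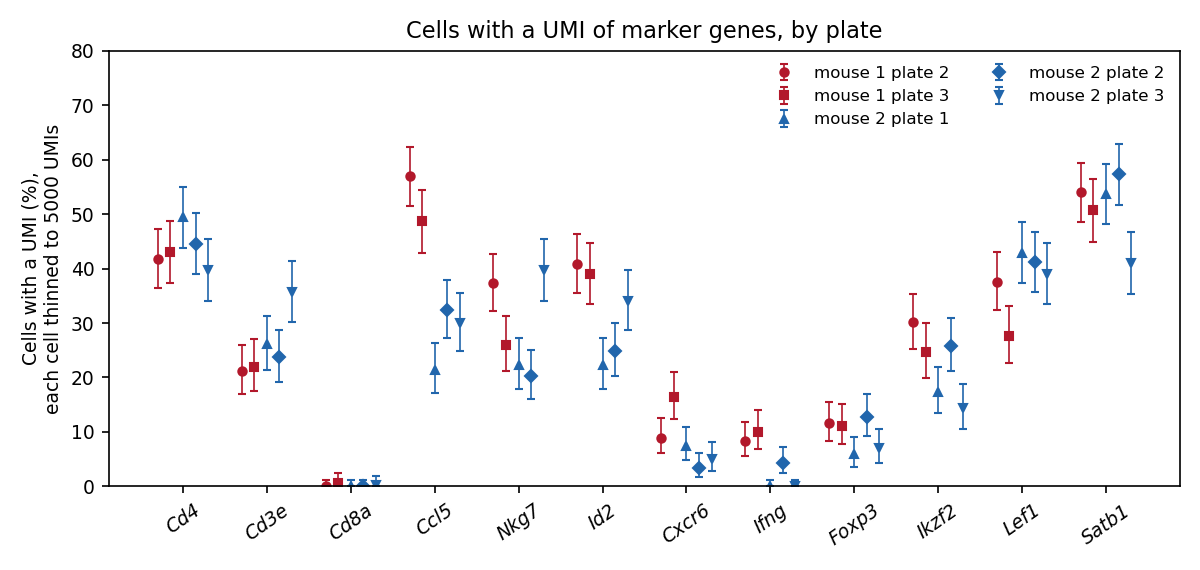
Percentage of cells with at least 1 UMI of 12 marker genes (vertical axis) in each of the 5 plates, after every cell was thinned to 5000 UMIs; points are plates, bars are exact 95% binomial intervals, red is mouse 1 and blue is mouse 2. Ccl5 lies at 57.0% and 48.7% in the plates of mouse 1 and between 21.4% and 32.4% in those of mouse 2, while Cd8a stays at or below 0.667%.

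The cells were grouped by similarity on 103 genes of fixed T cell gene lists, and 3 of the 6 clusters could be named from their markers. A Th1-like class of 339 cells scored highest on Th1 markers (1.28), with 12 of them raised. It also scored 0.656 on Th2 and 0.602 on cycling markers. A Treg-like class of 337 cells had 11 Treg markers raised, with Ikzf2, Gpr83, Ctla4, Foxp3 and Nrp1 among its top 10 genes. It scored 1.20 on Treg, 1.04 on Th17 and 0.662 on Tfh markers. A naive-like class of 333 cells had 6 naive markers raised but only Satb1 among its top 10 genes, so its name rests on weaker evidence. The other 3 clusters held 886 cells and were left unnamed. Of these, 1 with 263 cells had Xcl1 and Id2 among its top 10 genes. It scored 0.635 on natural killer cell and 0.568 on Th1 markers, with 2 natural killer markers raised. Another with 199 cells scored 0.544 on B cell markers, with 1 raised. Clusters with Xcl1 and Id2 were named Th1-like with all UMIs, another random split and 1 part of the list genes. The same held in cells of 1000 or more UMIs, but not at the higher resolution or standardised over all plates. No cluster of the main clustering had a Tfh-like, Th17-like, natural-killer-like, B-cell-like or myeloid-like name. Clustering on all UMIs gave a Tfh-like cluster of 92 cells, 3.46 to 5.77% of each plate, with 9 Tfh markers raised and Cxcr5 among its top 10 genes. With the values of each gene shuffled between cells of similar depth, 10 draws gave 69 clusters, of which 1 was named naive-like and 0 Th1-like or Treg-like. Against the other clusters, shuffled clusters had up to 12 genes called by edgeR, 6 of them outside the clustering genes. The Th1-like cluster had 22 (10 outside). The unnamed cluster of 199 cells, which scored highest on B cell markers, had the most, 31 (17 outside). The naive-like cluster had 3 and the Treg-like cluster 1 (0 outside in both), within the range of shuffled cells.

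The question of whether the animals differed in the make-up of their CD4 cells was asked through the class shares. Th1-like cells made up 19.5% ± 0.744 (SD, n = 2 plates) of cells in mouse 1 and 16.8% ± 2.21 (n = 3 plates) in mouse 2, a difference of -2.64 percentage points (exact two-sided permutation p = 0.2). Treg-like cells made up 15.8% ± 1.49 and 19.1% ± 1.68 (difference 3.33 percentage points, exact permutation p = 0.2), and naive-like cells 16.8% ± 1.12 and 18.1% ± 2.57 (difference 1.21 percentage points, exact permutation p = 0.7). The 5 plates have 10 splits into groups of these sizes, so 0.1 is the smallest p the design allows. Genes were standardised within each plate before clustering, which draws the plates' shares together; standardised over all plates at once, the Th1-like difference was -11.3 percentage points (exact permutation p = 0.2), and with clusters from the other part of the list genes it was 1.47. The Treg-like difference was 0.185 with another random split, 0.321 standardised over all plates and -1.45 with the other part of the list genes. At the lower and higher resolution it was 4.47 and 2.90 (exact permutation p = 0.1 each). The Th1-like difference was -3.62 at the higher resolution, -3.40 with another random split and -2.66 with 10 components (exact permutation p = 0.1 each). The shares themselves depend on the clustering as well: Th1-like cells made up 32.5% and 27.5% at the lower resolution, 36.1% and 33.4% with 10 components, and 38.7% and 36.2% in cells of 1000 or more UMIs. Treg-like cells ranged from 7.76% and 10.7% at the higher resolution to between 33.4% and 40.7% by plate at the lower one. Classes gated by single genes involve no standardisation. They held 342 Th1 cells in the 2 plates of mouse 1 and 351 in the 3 of mouse 2. The main clustering had 148 and 191. Gated Treg cells numbered 31 and 79, and gated naive cells 107 and 240. Ccl5 was 1 of the genes of the Th1 gate, and the gated shares were not tested.

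Th1-like cells were compared with naive-like cells to find what sets the effector cells apart, on UMIs that had been held out of the clustering. Among genes that played no part in the clustering, 4 were higher. Ccr2, the receptor that draws monocytes and effector T cells towards the chemokine Ccl2, was higher by a log2 fold change of 3.52 (SE 0.677; edgeR adjusted p = 0.0276). Myo1f, a myosin of haematopoietic cells, was higher by 2.86 (SE 0.438; edgeR adjusted p = 0.0038). AW112010, a transcript induced in activated lymphocytes and macrophages, was higher by 1.03 (SE 0.155; edgeR adjusted p = 0.0038), and Actb, cytoplasmic actin, by 0.19 (SE 0.0369; adjusted p = 0.0342). All 4 had the same sign in each mouse, with log2 ratios for Ccr2 of 3.74 and 3.02, for Myo1f of 3.26 and 2.56, and for AW112010 of 0.90 and 1.25. Ccr2 was 1 of the fixed markers by which the Th1-like class was named, and Actb counts followed those of Lrrc58 across cells (Pearson r 0.658 to 0.731 by plate). Without mouse 1 plate 2 the log2 fold changes were 3.79 for Ccr2, 2.21 for Myo1f, 0.78 for AW112010 and 0.13 for Actb. Their edgeR adjusted p were 0.357, 0.522, 0.607 and 0.814. The Ccr2 call was also lost without mouse 1 plate 3 (0.154) and mouse 2 plates 1 (0.0672) and 3 (0.145). In these fits its log2 fold change was 3.29, 4.55 and 3.13. The Actb call was lost without any of the plates of mouse 2 (0.0942, 0.0580 and 0.201 for plates 1, 2 and 3). There the Actb log2 fold change was 0.184, 0.210 and 0.155.

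Across all 9004 genes tested, edgeR called 15 higher and 13 lower in Th1-like than in naive-like cells at an adjusted p of 0.05. The balance of directions depends on the method: DESeq2 called 19 higher and 51 lower, wells with a UMI in place of UMIs gave 10 and 0, and edgeR without mouse 1 plate 3 gave 11 and 1. All 28 had the same sign in both mice, and 13 of them were clustering genes, which differ between the classes by construction. They describe what the class is made of. Ccl5 was higher by a log2 fold change of 3.38 (SE 0.160), Nkg7 by 2.97 (SE 0.310) and Id2, a transcription factor of effector T cells, by 1.64 (SE 0.240). A group of calcium-binding and membrane-associated proteins went with them: S100a6 (3.04), Anxa2 (3.01), Ahnak (2.84), S100a4 (2.58) and Lgals1 (2.30), together with Itgb1 (2.32), the beta-1 integrin that binds inflamed endothelium and matrix. Satb1, a chromatin organiser of resting T cells, was lower (-1.23, SE 0.161), as was Igfbp4 (-1.40, SE 0.240). Several markers of the response did not pass the test: Hopx (2.44, edgeR adjusted p = 0.0501), Cxcr3 (2.39, 0.0595), Lef1 (-1.08, 0.0592), Cxcr6 (2.00, 0.256) and Tbx21 (2.20, 0.527).

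**Figure D2:**
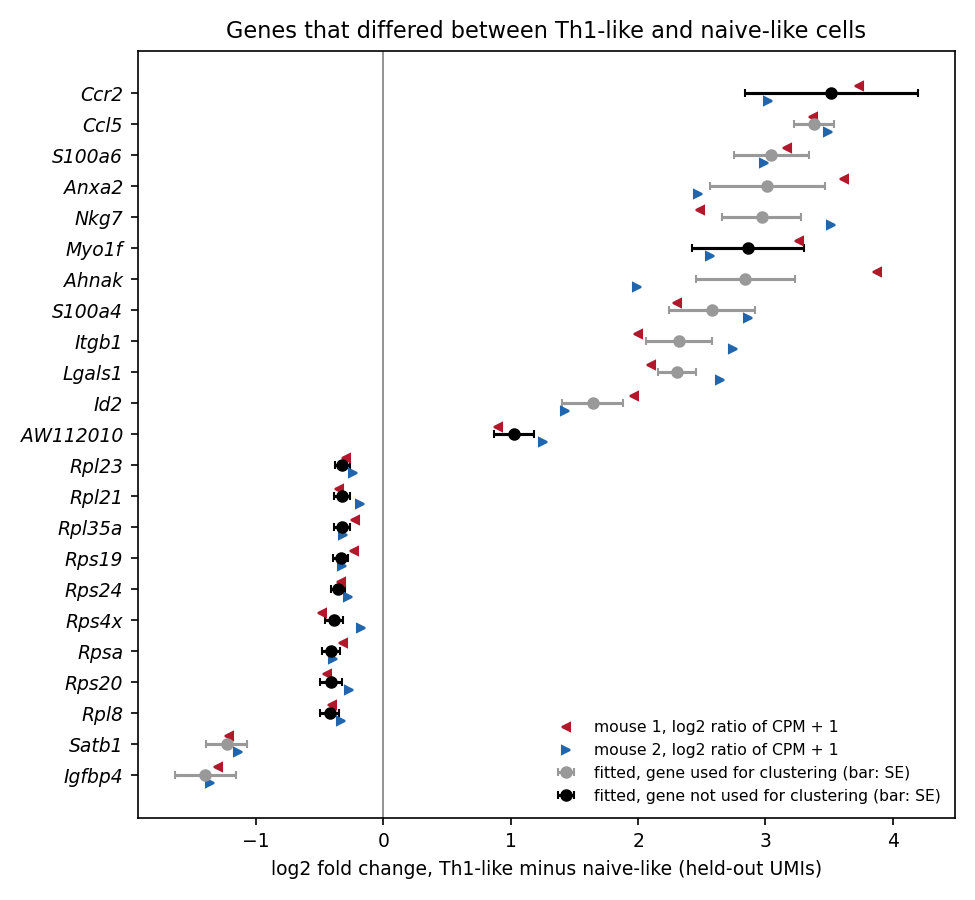
Fitted log2 fold change between Th1-like and naive-like cells (horizontal axis; circles, with bars of 1 SE) for called genes with the largest changes, with the log2 ratio of CPM plus 1 in each mouse (triangles, red for mouse 1 and blue for mouse 2). Grey circles are genes used for clustering; among the black circles, Ccr2, Myo1f and AW112010 are higher and the ribosomal protein genes lie between -0.42 and -0.32.

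Some of the fixed gene lists were called as groups; lists made up of clustering genes differ between the classes by construction. Of the 14 Th1 genes measured, 4 rose (Ccl5, Nkg7, Id2 and Ccr2), and 10 rose when adjusted over the list alone (camera adjusted p = 1.65e-24; adjusted p = 0.0201 with an estimated correlation); the list also named the class. Of 13 S100, annexin and galectin genes 7 rose, 10 when adjusted over the list alone (camera 3.61e-25; adjusted p = 0.0201 with an estimated correlation), of which 12 members were clustering genes. Of 11 genes for homing to inflamed tissue, 9 of them clustering genes, 2 rose, Itgb1 and Ccr2, and 6 when adjusted over the list alone (3.09e-12; adjusted p = 0.0389 with an estimated correlation). Of 10 effector transcription factors, 5 of them clustering genes, 1 rose, Id2, and 4 when adjusted over the list alone (1.09e-10; adjusted p = 0.0389 with an estimated correlation). Of 10 naive genes, all clustering genes that also named the reference class, 2 fell, Satb1 and Igfbp4, and 5 when adjusted over the list alone (9.87e-09; adjusted p = 0.0431 with an estimated correlation). Camera called 15 lists in all, and these 5 kept an adjusted p under 0.05 with an estimated correlation. Lists that lost it included the memory and stemness factors, of which 0 of 10 fell and 6 when adjusted over the list alone (1.62e-05; adjusted p = 0.0640 with an estimated correlation), with Foxp1 at -0.63 and Tcf7 at -0.56. The cycling list had 0 of 12 called and 3 higher when adjusted over the list alone (0.000266; adjusted p = 0.0826 with an estimated correlation), with Hmgb2, a chromatin protein, at 0.79 (edgeR adjusted p = 0.0738). The actin cytoskeleton list had 1 of 25 called, Actb, and 4 when adjusted over the list alone (0.00121; adjusted p = 0.0848 with an estimated correlation), with Arpc4, a subunit of the actin-nucleating Arp2/3 complex, at 1.16. The cytotoxic granule list had 1 of 8 called, Nkg7, both over all genes and adjusted over the list alone (0.0013; adjusted p = 0.175 with an estimated correlation). MHC class I processing genes were not called as a list by camera (limma, adjusted p = 0.264); Psmb8 was at 0.43 and B2m at 0.24.

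Ribosomal protein genes tended to be lower in Th1-like than in naive-like cells, and their call as a list depended on the correlation assumed between genes. None of the 84 was a clustering gene, and 83 of them had a negative log2 fold change, with a median of -0.22. The test called 11 as fallen over all genes and 53 adjusted over the list alone. The examples are Rps24 (-0.36, SE 0.0559, edgeR adjusted p = 0.00428), Rpsa (-0.41, SE 0.0694, adjusted p = 0.00994) and Rpl8 (-0.42, SE 0.0718, adjusted p = 0.0102). Rps4x, Rps19, Rps20, Rpl35a, Rpl21 and Rpl23 were called as well, at -0.39, -0.34, -0.41, -0.33, -0.32 and -0.32. As a list they had a camera adjusted p of 2.86e-14 (adjusted p = 0.0640 with an estimated correlation) and a fry adjusted p of 0.00581. Their share of held-out UMIs was lower in Th1-like than in naive-like cells in all 5 plates, at 27.1% against 29.9%, 25.6% against 29.4%, 27.7% against 31.1%, 29.1% against 30.3% and 25.7% against 29.8%. Translation factors were called down by camera (0 of 15 fallen, 2 when adjusted over the list alone; 0.0225; adjusted p = 0.175 with an estimated correlation), with Tpt1 at -0.31 and Npm1 at -0.35. None of these named genes kept its call in all 5 fits that left out 1 plate: Rpsa was called in 3, Rps24, Rpl8 and Rpl21 in 2, Rps4x, Rps19, Rpl35a and Rpl23 in 1 and Rps20 in 0. Without mouse 1 plate 2 Rps24 was at -0.40 (edgeR adjusted p = 0.0909) and Rpl8 at -0.43 (0.289), and both were also lost without mouse 1 plate 3 (0.118 each) and mouse 2 plate 3 (0.0608 and 0.144). Rpsa was at -0.29 without mouse 1 plate 3 (edgeR adjusted p = 0.587). The number of genes called lower outside the clustering genes went from 11 to 1 without mouse 1 plate 2, 1 without mouse 1 plate 3, 6 without mouse 2 plate 1, 13 without mouse 2 plate 2 and 2 without mouse 2 plate 3. It was 0 on wells with a UMI and 0 without the mouse as block. With another normalisation (RLE) it was 6, with sums per plate 17, with DESeq2 45 and with no low-count filter 47. These 4 alternatives kept the same classes. Where the classes were drawn another way it nearly vanished. It was 2 with another random split and 0 in cells of 1000 or more UMIs. It was also 0 with classes gated by single genes and with the other part of the list genes. The plates of either mouse alone gave 1. Counting wells with a UMI shows little of a change in genes with many UMIs per cell.

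**Figure D3:**
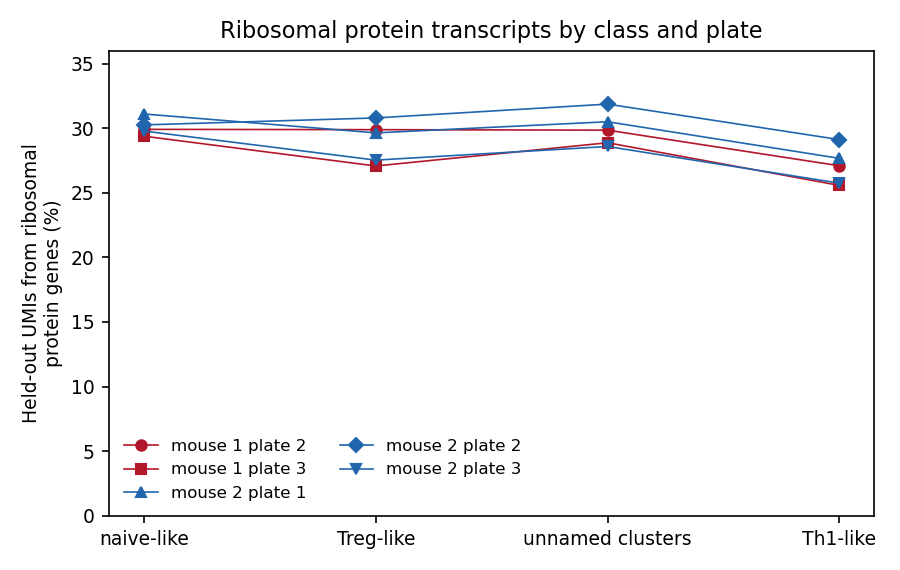
Percentage of held-out UMIs that came from the 84 ribosomal protein genes (vertical axis) in naive-like, Treg-like, unnamed and Th1-like cells; each line joins the values of 1 plate, red for mouse 1 and blue for mouse 2. The Th1-like value lies below the naive-like value in all 5 plates, for example 25.7% against 29.8% in mouse 2 plate 3.

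Treg-like cells were compared with naive-like cells in the same fit. Of 9004 genes, edgeR called 2 higher and 2 lower, all of them clustering genes with the same sign in both mice. Ikzf2, which encodes Helios, a transcription factor of Treg cells, was higher by a log2 fold change of 2.42 (SE 0.283; edgeR adjusted p = 0.00176). Nfkbia, the inhibitor of NF-kappa-B that is induced by it, was higher by 1.18 (SE 0.184; edgeR adjusted p = 0.0214). Satb1 was lower (-1.07, SE 0.161; edgeR adjusted p = 0.0214), as was Foxo1, a transcription factor that maintains resting T cells (-1.54, SE 0.255; adjusted p = 0.0353). Outside the clustering genes 0 were called by edgeR and 7 by DESeq2, with 627 of all genes at an unadjusted p under 0.05 in edgeR; Cox7b, a respiratory chain subunit, had the smallest p among them (0.87, edgeR adjusted p = 0.0706). Id3 (2.07, edgeR adjusted p = 0.0618), Gpr83 (2.10, 0.186), Ctla4 (3.30, 0.255), Nrp1 (1.80, 0.493) and Tnfrsf18 (1.15, 0.493) did not pass, nor did Igfbp4 (-1.26, 0.0865), S1pr1 (-1.14, 0.239) and Klf2 (-1.49, 0.495), which act in recirculation through lymphoid organs in the case of S1pr1 and Klf2. Of 12 Treg genes 1 rose, Ikzf2, and 7 when adjusted over the list alone (camera 2.06e-11; adjusted p = 0.0649 with an estimated correlation), and of 10 naive genes 1 fell, Satb1, and 7 when adjusted over the list alone (1e-12; adjusted p = 0.0649 with an estimated correlation). The Tfh list (0 of 13 called, also adjusted over the list alone; 0.00172) and the memory list (1 of 10 fallen, Foxo1; adjusted over the list alone 5 fell and 1 rose; 0.00291) lost the call as well (adjusted p = 0.228 with an estimated correlation for both). The Ikzf2 call held without each plate in turn, with edgeR adjusted p from 0.00156 to 0.0322. Ikzf2 was not called when the classes were gated by single genes, with Foxp3 for Treg cells. Nor was it called in cells of 1000 or more UMIs, where the 1 gene called was lower. The Satb1 and Foxo1 calls were lost without any 1 of the 5 plates (lowest adjusted p 0.0551 and 0.0558), and Nfkbia was called only without mouse 2 plate 1 (0.0257). In those 5 fits the log2 fold changes ran from -1.17 to -0.99 for Satb1, -1.94 to -1.26 for Foxo1 and 0.93 to 1.41 for Nfkbia.

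Whether the Th1-like or Treg-like profile differed between the animals was tested with an interaction of class and mouse on sums per plate. edgeR called 0 of 6472 genes for either class, with 370 and 378 genes at an unadjusted p under 0.05. Plates were the units here, so the test measures the spread between plates of the same animal and not between animals. Its recovery of changed genes was not tested on simulated data. The absence of called genes therefore does not show that the profiles were alike in the animals.

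The animals were compared over all kept cells of each plate, with plates as the units, so that the test measures the spread between plates of 1 animal and not between animals. No gene passed the test. The values of single genes are given as measured. Ccl5 had 874 and 586 CPM in the plates of mouse 1 and 224, 338 and 391 in those of mouse 2, a log2 fold change of -1.14 for mouse 2 over mouse 1 (SE 0.296; edgeR adjusted p = 1.00). Slamf6, a receptor of helper T cells that binds itself on B cells, had -1.02 (SE 0.248), Ly6c2 -1.06 (SE 0.330), Itgb7, an integrin chain for homing to the gut, -0.92, Cxcr6 -1.45 and Id2 -0.72. In the other direction, Id3, a factor of resting and memory T cells, had 1.41 (SE 0.363), Ezr, which links membrane to actin, 1.13 (SE 0.276), S100a4 1.04, Rps10 0.55 and Lef1 0.50. edgeR called 0 of 10375 genes, with 421 at an unadjusted p under 0.05, and DESeq2 called 42, of which 25 were higher and 17 lower in mouse 2. Plates of the mice did not overlap for 2088 genes, 20.1% of those tested, where chance gives 20%. On simulated data of the same size, this test recovered 1.49% of genes changed 2-fold, 20.9% of those changed 4-fold and 54.5% of those changed 8-fold. The changed genes were all at or above the median count, so recovery of genes with lower counts is not known.

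Of the gene lists, camera called 4 between the mice. The 15 Th1 genes were lower in mouse 2 as a group (median log2 fold change -1.05; camera adjusted p = 2.29e-05; adjusted p = 0.594 with an estimated correlation), as were the 11 genes for homing to inflamed tissue (0.0148; adjusted p = 0.669 with an estimated correlation). The 10 memory and stemness factors (0.0176; adjusted p = 0.669 with an estimated correlation) and the 84 ribosomal protein genes (0.00371; adjusted p = 0.726 with an estimated correlation) were higher in mouse 2. In each of these lists 0 members passed edgeR, over all genes or adjusted over the list alone, and fry called 0 lists. Among single genes, shares of thinned cells did not overlap between the mice for Ccl5 (52.8% ± 5.90 in mouse 1 and 27.9% ± 5.77 in mouse 2), Slamf6 (plates from 17.8% to 36.7%, a difference of -15.5 percentage points) and Cxcr6 (12.6% ± 5.22 and 5.29% ± 2.03), each with an exact permutation p = 0.1, the smallest the design allows. Of other Th1 genes, the plates did not overlap and were lower in mouse 2 for Ifng, Ly6c2, Klrg1 and Gzmb (exact permutation p = 0.1 each) and for Id2, Il18r1 and Ccr2 (0.2 each). They overlapped for Nkg7 (exact permutation p = 0.6), Tbx21 (0.4), Cxcr3 (0.3), Gzmk (0.5) and Fasl (0.7). Gzmb was near the floor, with a mean of 0.983% of thinned cells in mouse 1, at most 1.67% in a plate, and none in mouse 2. Ly6c2 counts followed those of Ly6c1 across cells (Pearson r 0.559 to 0.725 by plate). Lef1 was higher in mouse 2, at 32.6% ± 7.03 and 41.0% ± 1.93 (exact permutation p = 0.1).

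The comparison of Tfh-like with Th1-like cells could not be made on held-out UMIs, because a Tfh-like class was found only when all UMIs were clustered (92 cells, 39 from mouse 1 and 53 from mouse 2). With that clustering edgeR called 3 genes higher and 8 lower in Tfh-like than in Th1-like cells of 10421 tested. Of these 11 genes 8 were clustering genes, and since clusters and test share their UMIs the calls carry no error rate. Gating by single genes gave 30 Tfh cells, 11 in mouse 1 and 19 in mouse 2, below the 20 per mouse set for a test. T cell receptor V segments and the agreement between the sequencing runs were not analysed here: the table has 0 genes for receptor segments, and its counts do not keep the runs apart.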

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

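The tests in this part were chosen only after the result was seen. In mouse 1 plate 2, 364 of 384 wells had as their most correlated other well one whose tag differs at the fewest positions, where chance gives 18.2; the other plates had 41, 39, 28 and 32. It is placed here because it bears on how counts were assigned to wells, which the comparisons did not examine. Counts misassigned between wells with similar tags could produce it: the number was 20.02 times chance in that plate. Well names of the other plates that follow another order than the listed tags may explain why they lack it: their wells shared a partner between plates in a median of 14.97% of wells, against 0 to 0.781% for pairs with mouse 1 plate 2. A different tag set in those plates would give the same result, and 23 simple plate orders tried afterwards gave at most 42 wells. If wells exchange UMIs, sums over a whole plate change only through the wells left out, but shares of cells with a gene, sums per class and correlations across cells change too. With another tag order in the other plates this would hold for all 5 plates, and by how much was not tested.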

How the results depend on the processing

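Alternatives on wells with a UMI, leaving out Rn45s, cells not thinned for the Ccl5 share, other references, other list genes, standardisation and components were chosen after seeing the data; the rest were fixed before.

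Between the mice, edgeR called 0 genes and DESeq2 42. With plate number as a replicate block edgeR called 0 (285 at an unadjusted p under 0.05). The 4 lists called by camera became 0 with an estimated correlation and 0 with fry.

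For Th1-like against naive-like cells, 28 genes were called. DESeq2 called 70 (20 shared), no low-count filter 87, another random split 13, cells of 1000 or more UMIs 6, classes gated by single genes 1, the other part of the list genes 12, wells with a UMI 10, and no replicate block 3. All other T cells as the reference gave 17. Plates of mouse 2 alone gave 13 and of mouse 1 alone 6. Leaving out 1 plate gave 11 (mouse 1 plate 2), 12 (mouse 1 plate 3), 19, 31 and 17 (mouse 2 plates 1, 2 and 3). Of 17 settings, 16 called Ccl5 and Nkg7, 10 AW112010, 8 Myo1f and 5 Ccr2. Of 15 lists, 5 were left with an estimated correlation. Actb turned to -0.12 and B2m to -0.0872 on wells with a UMI, and Lef1 to 0.0053 with gated classes.

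For Treg-like cells, 4 genes were called. DESeq2 called 18, no low-count filter 22, sums per plate 7, another random split 2, cells of 1000 or more UMIs 1, gated classes 1, no replicate block 0 and wells with a UMI 0. Plates of mouse 2 alone gave 2 and of mouse 1 alone 0, and leaving out 1 plate gave 1, except 2 without mouse 2 plate 1. Of 17 settings, 12 called Ikzf2, but gated classes and cells of 1000 or more UMIs did not. Of 4 lists, 0 were left with an estimated correlation. With gated classes Igfbp4 turned to 0.0079 and Klf2 to 1.03.

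The Th1-like share difference (-2.64 percentage points) was -5.00 at a resolution divided by 2, -11.3 standardised over all plates together and 1.47 with the other part of the list genes. The Treg-like difference (3.33) was 1.68 from all UMIs, 0.185 with another random split, 1.46 in cells of 1000 or more UMIs, 0.321 standardised over all plates and -1.45 with the other part of the list genes. No naive-like class was found without splitting, at lower or higher resolution, with joint standardisation, with more components or with the first part of the list genes, so those contrasts could not be run. No cluster was named as other than T cells, so leaving none out changes nothing.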

Other observations

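The tests in this part were chosen only after the related results were seen. Across cells within plates, Ccl5 went with Nkg7 (Pearson r 0.404 to 0.547 over the 5 plates), with Id2 (0.210 to 0.430) and with Lgals1 (0.168 to 0.395), and Nkg7 went with Cxcr6 (0.191 to 0.269). S100a6 went with Anxa2 (0.173 to 0.354) and Itgb1 (0.141 to 0.327), and Itgb1 with Myo1f (0.125 to 0.325). Foxp3 went with Ikzf2 (0.0877 to 0.346) but not with Ccl5 (-0.121 to 0.0012), and its correlation with Ctla4, another Treg marker, changed sign between plates (-0.106 to 0.450). Ccl5 with S100a4 ranged from -0.00903 to 0.210. These pairs were picked from 13663378, and cells of 1 plate are not independent replicates.

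Gata3, the lineage factor of Th2 cells that other T cells also express, had a UMI in 34.3% ± 2.90 (SD, n = 2 plates) and 36.5% ± 1.65 (SD, n = 3 plates) of thinned cells. The interferon-induced gene Isg15 had one in 11.8% ± 1.53 and 12.4% ± 4.36. Mki67, a marker of dividing cells, was at most 0.932% in any plate.

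Cd8b1 UMIs in CD4 T cells were weighed against CD8 T cells and against shared reads. The share of cells with a Cd8a UMI was at most 0.0538 of the share with Cd8b1, which speaks against CD8 T cells. Cd8b1 and Gnal, on different chromosomes, correlated at 0.297 or more in every plate, so reads shared between genes may account for the Cd8b1 counts.

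Ccl5 was seen in more cells of mouse 1. Depth per cell does not account for it, as the lowest share in a plate of mouse 1 was 48.7% after thinning. A few wells do not either: without the 10 wells with the most Ccl5 UMIs in each plate, 118% of the log2 ratio was left (1.20 to 1.41). Whether animals or plates differ could not be decided, since the exact permutation p of 0.1 is the smallest possible; a stronger type 1 response in mouse 1 may be 1 reading, and a difference in handling another. More animals with several plates each would separate them.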
